A study of Mus musculus with 121 samples.

How the data were processed

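Liver and gonadal adipose tissue of C57BL/6 mice were profiled by RNA sequencing. Per the labels' protocols, RNA with an integrity number above 7 was extracted with a column kit, stranded mRNA libraries were made from polyadenylated RNA, and single-end reads of 50 bases were read on a HiSeq instrument. STAR 2.5.1b, featureCounts 1.5 and the mouse build GRCm38.p5 are named in the submitters' processing notes. Their settings, the strand option and the annotation release are not given in the sources used here. The deposited values are raw read counts per Ensembl gene, 1 table for each tissue, as their whole numbers and unequal totals show. Reads of near-identical gene copies (serum amyloid, major urinary protein, immunoglobulin, class II and Cyp2 genes) and of overlapping or antisense genes may have been split or lost in that counting, so their values are uncertain.

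Each table held 25759 genes, of which 25723 had a symbol in the GRCm38 gene annotation used and 36 did not. Groups were taken from the labels as tissue, diet and genotype. Of 121 labelled samples 120 had a column. The labelled chow WT sample 1 of gonadal adipose tissue had none and was not analysed here, and 1 column without a label was not used. The liver table gave 75 libraries, and 45 came from the gonadal table. Mice of the same number appear in both tissues, so the tissues are not independent samples. No pair of libraries within a group agreed within sampling noise: over 392 pairs of libraries with at least 100000 counts, the ratio of the observed to the sampling spread was at least 3.35. The p-values measure the spread between mice.

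Counts were analysed in R 4.3.3 with edgeR 4.0.16. In all, 3 fits were made, each over all its groups so that they share an estimate of the spread: liver on chow and HFD, liver on Control and Alios, and gonadal adipose tissue. Genes were kept by edgeR's expression filter (minimum count 10, minimum total 15), libraries were scaled by TMM, and dispersions were estimated before the quasi-likelihood fit and test. This left 11064, 11595 and 14536 genes. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Tests were two-sided. SE of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values used TMM-scaled library sizes. A group with 1 library (KO on Control) entered no test.

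Named genes followed a rule fixed before the data were examined: Pepd, Prep, Dpp4 and Fap, up to 8 genes with the highest and 8 with the lowest log2 fold change among called genes with at least 1 CPM in a group (5 each way for differences of effects), and up to 3 called members of each gene list with the smallest adjusted p. Some genes that this rule names are not reported here. Predicted genes and pseudogenes were left out. Cyp2b10, Cyp2c29 and Cyp2c55 on chow and on Control were chosen after their values were seen. The 37 gene lists were also fixed before the data were examined, 30 for liver and 29 for adipose tissue. Each was counted over all genes tested and adjusted over the list alone, and tested with camera in limma 3.58.1 at its preset correlation of 0.01, with an estimated correlation and with fry. Of all list calls at the preset correlation, that of interferon-stimulated genes in the adipose difference of KO effects held with an estimated correlation. Summed marker levels of epididymis, testis, skeletal muscle, pancreas and hepatocytes were computed per library as a measure of other tissue.

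The test was tried on counts simulated for each gene independently, without outlying mice or other tissue, with 100 genes changed by 2-fold and 100 by 4-fold. For KO against WT on HFD in liver it called 92 % and 99 % of them, and for the difference of KO effects in adipose tissue 48 % and 78 %. Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE size factors, no filter on low counts, a mean of at least 1 CPM, a fit of only the groups compared, all 12 liver groups in a fit, the replicate number as a block, the run of mouse numbers as a covariate, each library of a group of 2 to 5 left out, the target's chromosome left out and an adjusted p under 0.01. A sex covariate was not fitted, because the Y-linked gene Ddx3y was at 16.3 CPM or more in every library. Fits without the mouse labelled HET, without libraries with much muscle, epididymis or liver RNA, without the library of lowest total, and the comparison of HFD with chow in HET mice were added after the data were seen. For each comparison, 100 splits of the same libraries into groups of the same sizes were drawn and refitted where that many exist.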

Results

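Gene expression was measured by RNA sequencing in liver and gonadal adipose tissue of C57BL/6 mice that were wild type (WT), heterozygous (HET) or knockout (KO) for a gene the labels write as PEP. Mice ate standard chow, a high-fat diet (HFD), a Control diet or an Alios diet for 18 weeks from 8 weeks of age. Liver was measured on all 4 diets, with 5 WT, 8 HET and 5 KO mice on chow, 8, 11 and 9 on HFD, 5, 4 and 1 on Control, and 6, 5 and 8 on Alios. Gonadal adipose tissue was measured on chow in 4 WT, 8 HET and 5 KO mice and on HFD in 8, 11 and 9. Total counts ran from 42692 to 8854246 in the 75 liver libraries (median 3191160, the next lowest 1027087) and from 4236655 to 6699887 in the 45 adipose libraries. The lowest liver total belonged to Alios KO library 8. Levels below are library-size-scaled counts (CPM) with their SD, changes are log2 fold changes with their SE, and adjusted p-values come from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

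The targeted gene was taken to be Pepd, from knowledge of the study. It encodes prolidase, an enzyme that splits dipeptides ending in proline or hydroxyproline. Pepd (ENSMUSG00000063931) lies on chromosome 7 from 34912379 to 35044708, plus strand, in GRCm38. In liver on chow, Pepd stood at 43 ± 3.83 CPM in WT (n = 5), 21.6 ± 2.07 in HET (n = 8) and 1.65 ± 1.13 in KO (n = 5). On HFD the means were 53.1, 23.5 and 1.78 CPM, on Control 44.3, 22 and 2.15 (1 KO library), and on Alios 42.7, 25.1 and 2.26. KO livers held 28.9-fold less Pepd than WT on chow (log2 -4.85 ± 0.38, edgeR adjusted p = 1e-12, lower in 5 of 5), 28.8-fold less on HFD (edgeR adjusted p = 7e-20, 9 of 9) and 16-fold less on Alios (log2 -4.00 ± 0.13, edgeR adjusted p = 2.1e-19, 8 of 8). Gonadal adipose tissue of KO mice kept more of it: 17.8 ± 11.3 CPM against 83.8 ± 17.8 in WT on chow (log2 -2.23 ± 0.28, edgeR adjusted p = 1.1e-05) and 25.2 ± 6.7 against 103 ± 9.3 on HFD (log2 -2.03 ± 0.20, edgeR adjusted p = 2.1e-08). Prep and Dpp4, which also cleave next to proline, passed the test in no liver comparison. Prep was 1.37-fold lower in KO adipose tissue on chow (edgeR adjusted p = 0.0047), while Fap was at 13.3 ± 4.97 against 20 ± 9.9 CPM there (edgeR adjusted p = 0.12). In 1 mouse labelled HET on HFD, liver library 8 and adipose library 3, Pepd was at 1.22 CPM in liver and 21.8 CPM in adipose tissue, levels of the KO libraries, so this mouse is called the mouse labelled HET throughout.

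**Figure D1:**
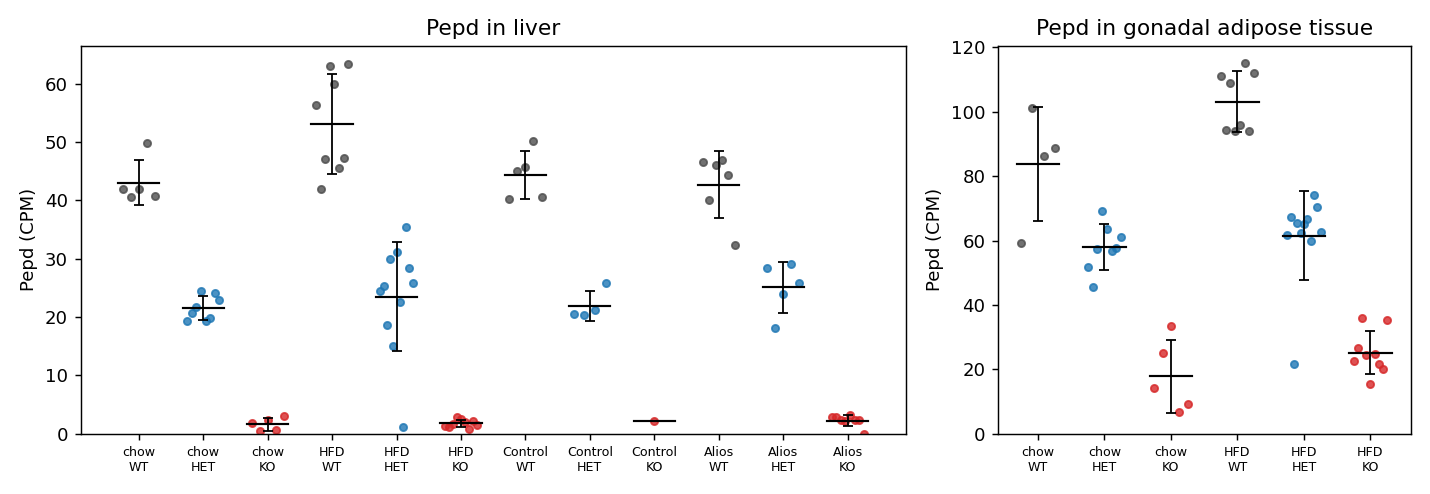
Pepd in CPM (y axis) in each liver library (left) and gonadal adipose library (right), by diet and genotype; bars give the mean and SD. KO libraries lie lowest in each diet, at 0 to 3.16 CPM in liver and 6.71 to 35.8 CPM in adipose tissue, and the library labelled HET at 1.22 CPM in liver lies among them.

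In liver on chow, KO mice had higher levels of acute-phase, macrophage and antigen-presentation genes than WT mice, and lower levels of genes of fatty acid oxidation. Saa2, an acute-phase serum amyloid, stood at 7900 ± 9370 CPM in KO against 128 ± 256 in WT, 60.7-fold higher (log2 5.92 ± 1.62, edgeR adjusted p = 0.03), but only 3 of the 5 KO libraries lay above every WT library. The metallothioneins Mt2 and Mt1 were 43.3-fold (edgeR adjusted p = 0.017) and 37.6-fold higher (edgeR adjusted p = 0.0086), each above every WT library in 4 of 5. Saa3 was 15.2-fold higher, in 5 of 5 (edgeR adjusted p = 0.00082), and haptoglobin (Hp) 4.02-fold higher, in 3 of 5 (edgeR adjusted p = 0.0077). Among lower genes, the fatty acid hydroxylases Cyp4a14 and Cyp4a10 were 7.86-fold (edgeR adjusted p = 0.013) and 4.1-fold lower (edgeR adjusted p = 0.038), each below the WT mean in 5 of 5.

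Of 24 macrophage markers tested, 14 rose over all genes tested and 20 adjusted over the list alone, with Tyrobp 3.32-fold higher, C1qc 3.28-fold and Cd5l 3.36-fold (camera adjusted p = 5.7e-18 with its preset correlation, adjusted p = 0.14 with an estimated correlation). Of 20 acute phase proteins 8 rose, and 11 adjusted over the list alone (camera adjusted p = 6.3e-09, adjusted p = 0.24 with an estimated correlation). Of 7 class II antigen-presentation genes 5 rose, 6 adjusted over the list alone, among them H2-DMb1 (4.26-fold) and H2-Ab1 (3.16-fold), with adjusted p = 0.14 with an estimated correlation. Of 23 interferon-stimulated genes 2 rose, Zbp1 and Stat2, and 14 adjusted over the list alone (adjusted p = 0.14 with an estimated correlation). Both tested neutrophil markers, Csf3r and S100a9, rose, as did 2 of 10 cytokines and chemokines, Ccl6 and Ccl5. Of 25 genes of fatty acid oxidation and PPAR alpha response, 7 fell and 17 adjusted over the list alone, including Ehhadh (1.74-fold lower), with camera adjusted p = 1.4e-16 and adjusted p = 0.14 with an estimated correlation. Slco1a4 fell among 18 genes of bile acid transport, and Ctss and Aldh18a1 were the called members of the matrix protease and proline metabolism lists. Of 13 endothelial markers Kdr fell and Cdh5 rose. Summed hepatocyte markers ran from 57800 to 125000 CPM in the KO libraries and from 98800 to 140000 in the WT libraries, and skeletal muscle markers reached 205 CPM in KO library 5 and 318 CPM in WT library 3.

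In all, 273 genes were higher and 103 lower among 11064 tested in this comparison. The count came to 1 (Pepd) when the chow WT and KO groups were fitted without the other groups, and to 617 in a fit of all 12 liver groups. It was 22 without KO library 2, 151 without KO 3, 148 without KO 5, 138 without WT 2 and 230 without WT 5, but 758 without KO 1, 1055 without KO 4 and 642 without WT 4. Of 36 named genes, 7 kept their call without each of the 10 libraries: C1qc, Cd5l, Kdr, Pepd, Saa3, Tyrobp and Zbp1.

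In heterozygous livers Pepd was the only gene called on HFD, Control and Alios, and no gene was called on chow. Pepd was 2.19-fold lower on HFD (log2 -1.13 ± 0.17, edgeR adjusted p = 0.00038, lower in 11 of 11, the mouse labelled HET with Pepd at the KO level included), 2.03-fold lower on Control (edgeR adjusted p = 2.5e-05, 4 of 4) and 1.65-fold lower on Alios (edgeR adjusted p = 0.0015, 5 of 5). On chow it was lower by a like amount, below every WT library in 8 of 8 (log2 -1.0 ± 0.21, edgeR adjusted p = 0.12), and it was called in a fit of these 2 groups (log2 -0.99, edgeR adjusted p = 0.00013). Without WT library 4, 1 gene other than Pepd was called there (Pepd edgeR adjusted p = 0.75). The 0 genes called by edgeR on chow compare with 494 at an unadjusted p under 0.05 and 0 by DESeq2. At an unadjusted p under 0.05 there were 924 genes on HFD, 331 on Control and 321 on Alios, and DESeq2 called 16 genes on HFD, 1 on Control and 1 on Alios. None of the 30 gene lists had a member called in any of these 4 comparisons. Over the list alone, 9 of 12 pancreas markers were lower in HET on Control, where WT livers reached 385 CPM of summed pancreas markers and HET livers 33.9, and adjusted p = 0.83 with an estimated correlation. The HET effect on Alios did not differ from that on Control for any gene by edgeR (0 genes, 314 at an unadjusted p under 0.05, 0 by DESeq2).

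On HFD, KO livers had higher levels of a small set of cytochromes P450 than WT livers, and lower levels of some collagen, lipid droplet and interferon-stimulated genes. Cyp2b10 (ENSMUSG00000030483, chromosome 7, 25897620 to 25926624), a drug-metabolizing cytochrome P450, stood at 83.6 ± 46.4 CPM in KO (n = 9) against 1.3 ± 0.864 in WT (n = 8), 61.5-fold higher (log2 5.94 ± 0.96, edgeR adjusted p = 0.00055). Cyp2c29 (chromosome 19, 39269405 to 39330713) stood at 2990 ± 968 against 581 ± 336 CPM, 5.14-fold higher (edgeR adjusted p = 0.00064), and all 9 KO libraries lay above every WT library for both genes. Cyp2c55 was 3.45-fold higher (edgeR adjusted p = 0.019), above every WT library in 8 of 9. Cyp2b and Cyp2c genes have close relatives whose reads the counting could split, so these 3 levels are uncertain to that extent.

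Of 28 collagen and matrix genes, 8 fell in KO on HFD, and 15 fell and 1 rose adjusted over the list alone. Col1a1 was 3.79-fold lower (3.95 ± 1.83 against 14.8 ± 9.87 CPM, edgeR adjusted p = 0.0074), Col1a2 2.61-fold and periostin (Postn) 2.19-fold lower, each below the WT mean in 9 of 9. The list gave camera adjusted p = 9e-10, and adjusted p = 0.32 with an estimated correlation. Pdgfrb fell among 13 hepatic stellate cell markers. Timp2, which encodes an inhibitor of matrix proteases, fell among 12 genes of the matrix protease list. Of 13 lipid droplet genes 4 fell, and 8 adjusted over the list alone. Cidea was 7-fold lower (3.85 ± 4.87 against 26.6 ± 25.4 CPM, edgeR adjusted p = 0.04), the adipogenic receptor gene Pparg 1.93-fold and the droplet coat gene Plin2 1.56-fold lower, with adjusted p = 0.32 with an estimated correlation. In a fit of these 2 groups Cidea, Pparg and Plin2 were not called (edgeR adjusted p = 0.079, 0.054 and 0.068). Of 23 interferon-stimulated genes 4 fell, 6 adjusted over the list alone, including Usp18 (1.98-fold lower, edgeR adjusted p = 0.0042) and Ifi44 (2.3-fold lower), with adjusted p = 0.32 with an estimated correlation. Of 19 xenobiotic cytochromes P450, 4 rose and 8 adjusted over the list alone, with adjusted p = 0.32 with an estimated correlation. Of 17 stress and unfolded protein response genes 2 rose, Hyou1 (1.7-fold, edgeR adjusted p = 0.016) and Hspa5 (1.46-fold, edgeR adjusted p = 0.034), and 7 adjusted over the list alone, with adjusted p = 0.32 with an estimated correlation. Hspa5 was not called in a fit of these 2 groups (edgeR adjusted p = 0.054). The growth factor receptor gene Egfr was 2.68-fold higher (480 ± 217 against 180 ± 56.6 CPM, edgeR adjusted p = 0.032). Crp rose among 20 acute phase proteins, Gsta1 and Gsta4 fell among 19 glutathione genes, Cxcl14 fell among 10 cytokines, and Acot2 and Plin2 fell among 25 genes of fatty acid oxidation. In all, 63 genes were higher and 127 lower among 11064 tested. The count came to 80 in a fit of these 2 groups, of which 68 were among the 190. Of 34 named genes 16 kept their call in every refit at an adjusted p under 0.05, among them Cyp2b10, Cyp2c29, Cyp2c55, Col1a1 and Usp18. The removal of chromosome 7, which holds Cyp2b10, is not counted. No refit left out a single library here, since both groups held more than 5, so dependence on single mice was not tested.

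**Figure D2:**
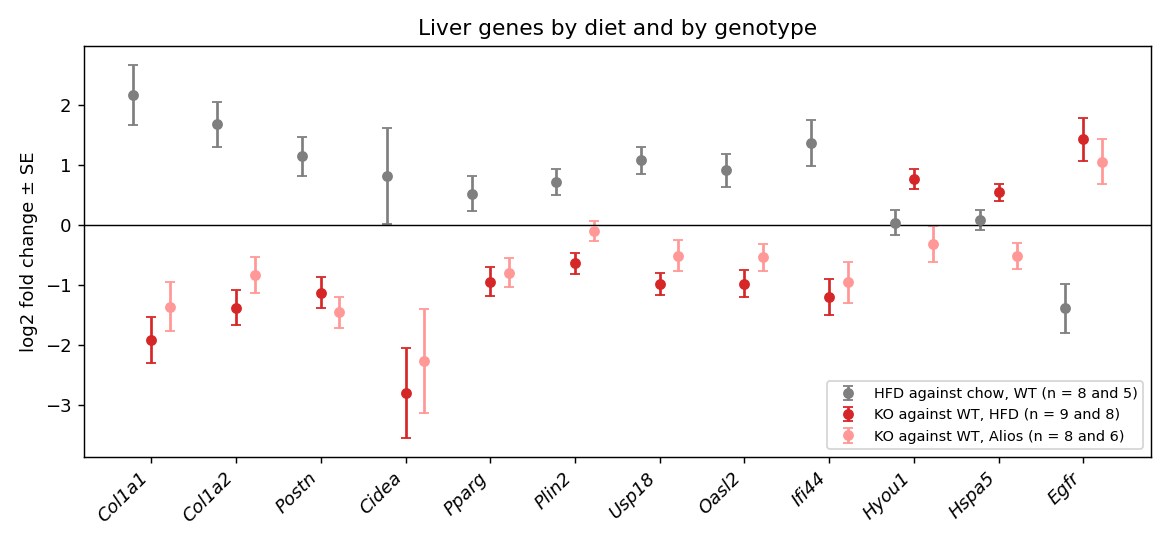
Log2 fold change (y axis, points, with SE as bars) of 12 liver genes between HFD and chow in WT, between KO and WT on HFD, and between KO and WT on Alios. Col1a1 stood at 2.17 for the diet in WT, at -1.92 for KO on HFD and at -1.37 for KO on Alios, and only the first 2 passed the test. These 2 comparisons share the WT libraries on HFD, which enter them with opposite sign. Opposite directions between them may therefore arise in part by construction.

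WT livers had higher levels of collagen and stellate cell genes on HFD than on chow, and lower levels of drug-metabolizing genes, among 134 higher and 73 lower genes. Apoa4, which encodes an apolipoprotein, stood at 1930 ± 1390 CPM on HFD (n = 8) against 180 ± 96.8 on chow (n = 5), 10.7-fold higher (edgeR adjusted p = 0.002, 8 of 8). Col1a1 was 4.5-fold (edgeR adjusted p = 0.016), Col1a2 3.2-fold and Col3a1 2.84-fold higher, and the macrophage genes Gpnmb and Trem2 were 13.7-fold and 8.81-fold higher, the WT levels on chow being 0.288 and 0.34 CPM. The hormone gene Fgf21 was 9.26-fold higher (edgeR adjusted p = 0.021). Among lower genes, the retinoic acid hydroxylase Cyp26a1 was 5.39-fold lower (edgeR adjusted p = 0.0025, below every chow library in 8 of 8), and the urinary protein gene Mup7 fell from 4630 ± 1720 to 953 ± 822 CPM (edgeR adjusted p = 0.029). The Mup genes are near-identical copies whose counts are uncertain.

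Of 28 collagen and matrix genes 8 rose, and 19 adjusted over the list alone (adjusted p = 0.1 with an estimated correlation). Of 13 stellate cell markers 3 rose, Colec11, Rgs5 and Pdgfrb, and 7 adjusted over the list alone (adjusted p = 0.097 with an estimated correlation). Of 23 interferon-stimulated genes Usp18 and Ifi44 rose, and 11 adjusted over the list alone (adjusted p = 0.1 with an estimated correlation). Of 19 xenobiotic cytochromes P450, 4 fell, including Cyp1a2 and Cyp2c50, and Cyp2b9 rose, against 12 lower and 2 higher adjusted over the list alone (adjusted p = 0.097 with an estimated correlation). Of 19 sex-biased liver genes 3 fell and 1 rose, and 10 fell and 4 rose adjusted over the list alone (adjusted p = 0.1 with an estimated correlation). Of 20 genes of fatty acid synthesis 3 rose, among them the desaturases Fads2 (2.45-fold) and Fads1 (1.72-fold), and Mlxipl fell. Cpt1a and Fgf21 rose among 25 genes of fatty acid oxidation, Apoa4 among 13 lipid droplet genes, Mmp12 among 12 matrix proteases, Srxn1 among 19 glutathione genes and Mcm2 among 14 cell cycle genes. The count of 207 came to 82 in a fit of these 2 groups, and to 48 without chow WT library 1, 89 without WT 3 and 106 without WT 5.

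The KO effect on HFD was lower than that on chow for 16 liver genes and higher for 0 (edgeR, 2003 at an unadjusted p under 0.05, 43 higher and 125 lower by DESeq2). They included the interferon-stimulated genes Usp18 (log2 difference -1.67 ± 0.32, edgeR adjusted p = 0.023), Oasl2 and Irf7, the chemokine gene Cxcl14 (-3.73 ± 0.81, edgeR adjusted p = 0.045) and the macrophage marker Tyrobp (-1.68 ± 0.38, edgeR adjusted p = 0.048). Of 23 interferon-stimulated genes 3 passed and 19 adjusted over the list alone (adjusted p = 0.066 with an estimated correlation), and of 24 macrophage markers 1 passed and 18 adjusted over the list alone (adjusted p = 0.17 with an estimated correlation). The edgeR count came to 0 in a fit of these 4 groups (1674 at an unadjusted p under 0.05). It was 0 without chow KO 2, KO 5, WT 2, WT 3 or WT 5, 1 without KO 3, 78 without WT 1, 423 without KO 1, 460 without KO 4 and 463 without WT 4.

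On the Alios diet, KO livers again had higher Cyp2b10, Cyp2c29 and Cyp2c55 than WT livers. Cyp2b10 stood at 54 ± 15.4 CPM in KO (n = 8) against 0.999 ± 1.2 in WT (n = 6), 47.4-fold higher (log2 5.57 ± 0.52, edgeR adjusted p = 1.3e-07), and Cyp2c29 at 2910 ± 423 against 535 ± 245, 5.44-fold higher (edgeR adjusted p = 2e-05). Cyp2c55 was 3.43-fold higher (edgeR adjusted p = 0.019), and for all 3 genes 8 of 8 KO libraries lay above every WT library. KO library 8, with 42692 counts, is among these. A single read came to 21.3 CPM at its depth, which is also the highest Cyp2c55 level of the group. Cyp2c55 kept its call without this library. Cyp2c55 was not called in a fit of all 12 liver groups (edgeR adjusted p = 0.056) or with the replicate block (edgeR adjusted p = 0.057). Lower genes included the monocarboxylate transporter gene Slc16a5 (6.67-fold, edgeR adjusted p = 0.001, 8 of 8), the sterol-binding protein gene Osbpl3 (5.78-fold, edgeR adjusted p = 0.019), the organic anion transporter gene Slco1a4 (3.74-fold, edgeR adjusted p = 0.024) and Postn (2.76-fold, edgeR adjusted p = 0.0049, 7 of 8). Of 29 collagen and matrix genes Postn fell and Col15a1 rose (2.33-fold), against 14 lower and 2 higher adjusted over the list alone (camera adjusted p = 6.4e-08, adjusted p = 0.32 with an estimated correlation). Of 19 xenobiotic cytochromes P450 the 3 named above rose, and 8 rose and 2 fell adjusted over the list alone, while the list's median log2 change was -0.041 (adjusted p = 0.28 with an estimated correlation). Over the list alone, 6 of 23 interferon-stimulated genes and 6 of 13 lipid droplet genes were lower, with 0 over all genes tested by edgeR in either list (adjusted p = 0.33 and 0.32 with an estimated correlation). In all, 14 genes were higher and 12 lower among 11595 tested. The count was 65 by DESeq2, 53 in a fit of these 2 groups, 40 with RLE size factors, 22 without KO library 8 and 8 with the replicate block. Of 17 named genes 5 kept their call in every refit at an adjusted p under 0.05: Cyp2b10, Cyp2c29, P2rx3, Pepd and Slc16a5.

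**Figure D3:**
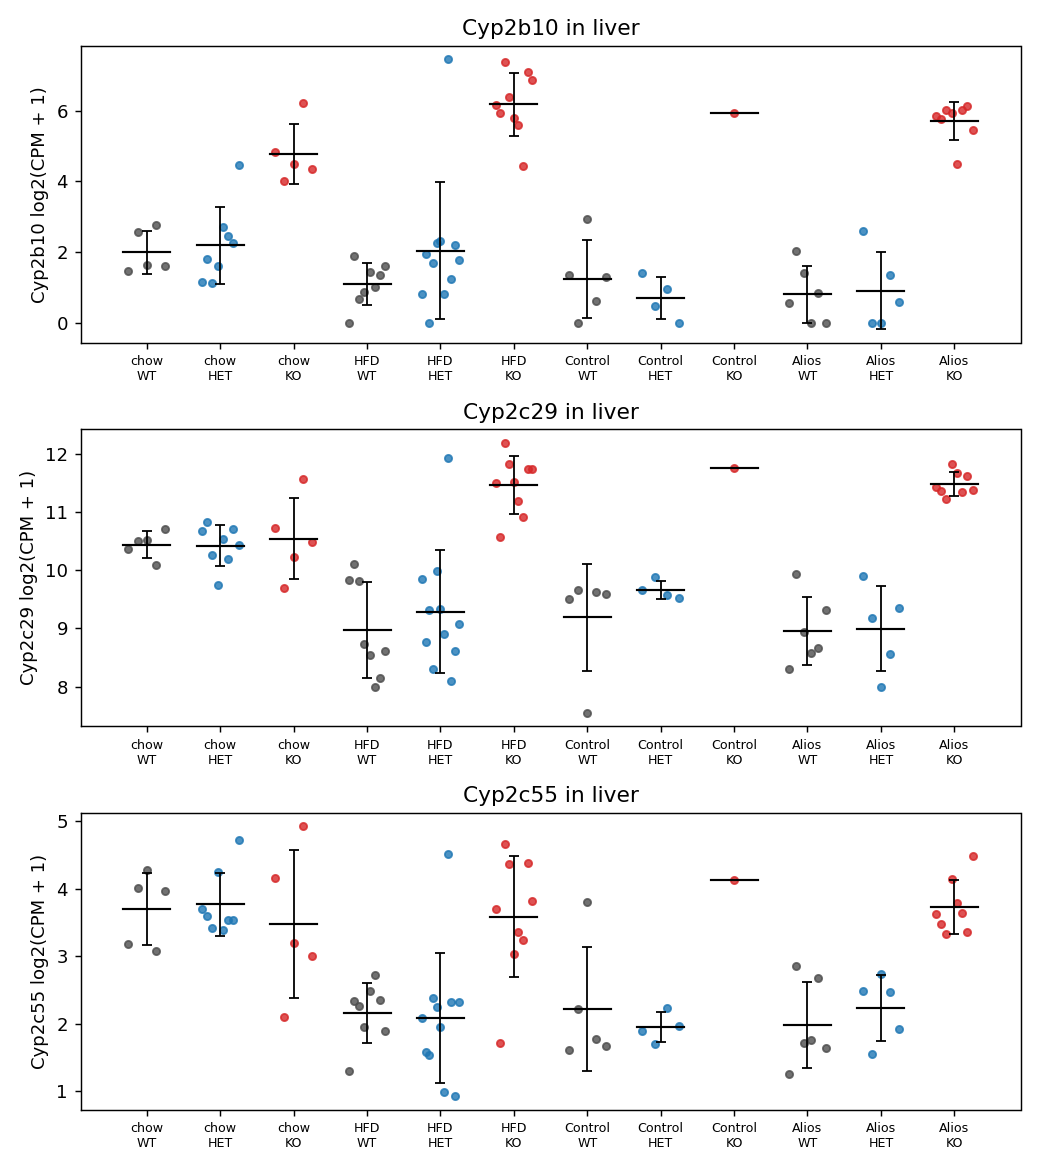
Cyp2b10, Cyp2c29 and Cyp2c55 as log2(CPM + 1) (y axis) in each liver library by diet and genotype; bars give the mean and SD. On HFD the KO libraries hold 20.6 to 164 CPM of Cyp2b10 and the WT libraries 0 to 2.71, and the high point among HET libraries on HFD, at 174 CPM, is the mouse labelled HET whose Pepd was at the KO level.

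The Control diet had 1 KO library, which allows no test. Its Pepd was at 2.15 CPM against 40.2 to 50.2 in 5 WT libraries. On chow all 5 KO libraries lay above every WT library for Cyp2b10, at 15.1 CPM or more against at most 5.75. Its means were 31.2 CPM in KO against 3.29 in WT (log2 3.37 ± 1.14, edgeR adjusted p = 0.0795), a difference that did not pass the test. Cyp2c29 and Cyp2c55 on chow did not pass it either, at log2 0.23 ± 0.47 (edgeR adjusted p = 0.84) and 0.15 ± 0.48 (edgeR adjusted p = 0.911). The spread in these tests was estimated over all chow and HFD livers, among them the mouse labelled HET, at 174 CPM of Cyp2b10. Whether that mouse kept Cyp2b10 from passing on chow was not tested by leaving out only this mouse. In a fit of only the chow WT and KO livers, Pepd was the only gene called. Between Alios and Control in WT livers, edgeR called 0 of 11595 genes, with 976 at an unadjusted p under 0.05 and 0 by DESeq2, and 2 genes were called without Control WT library 3. Over the list alone, 2 of 13 lipid droplet genes were higher on Alios (camera adjusted p = 1.5e-05, adjusted p = 0.31 with an estimated correlation), and all 12 pancreas markers were lower (adjusted p = 0.67 with an estimated correlation). Summed pancreas markers were at 385 CPM in 1 Control WT library and at most 29.7 in Alios WT libraries. In simulated counts for this comparison, 75 % of genes changed by 2-fold and 94 % of those changed by 4-fold were called. Those counts held no outlying mouse, other tissue or correlation between genes, so the shares need not hold for the real libraries.

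In gonadal adipose tissue on chow, KO mice had higher levels of interferon-stimulated, neutrophil and antigen-presentation genes than WT mice, and lower levels of some genes of fatty acid and cholesterol synthesis. Oas2 (ENSMUSG00000032690, chromosome 5, 120730333 to 120749853), an antiviral enzyme induced by interferon, stood at 109 ± 59.9 CPM in KO (n = 5) against 21.7 ± 3.67 in WT (n = 4), 5.01-fold higher (log2 2.32 ± 0.34, edgeR adjusted p = 0.00011), above every WT library in 4 of 5. Cd79a, a part of the B cell receptor, was 22.6-fold higher (106 ± 120 against 4.66 ± 2.41 CPM, edgeR adjusted p = 0.00087, 4 of 5), and the neutrophil gene S100a9 77.7-fold higher (edgeR adjusted p = 0.00011, 4 of 5). Fasn, which encodes fatty acid synthase, was 2.96-fold lower (1590 ± 1330 against 4690 ± 1710 CPM, edgeR adjusted p = 0.017) and the hormone gene Lep 3.65-fold lower (edgeR adjusted p = 0.021). Fasn was not called without KO library 4, KO 5 or WT 5 (edgeR adjusted p = 0.068, 0.065 and 0.081), nor Lep without KO 4, KO 5, WT 3 or WT 5 (edgeR adjusted p = 0.065, 0.06, 0.055 and 0.14). Of 69 named genes 27 kept their call without each of the 9 libraries, among them Oas2, Cd79a and S100a9 but not Fasn, Lep, Scd2 or Dgat2.

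Of 23 interferon-stimulated genes 19 rose, and 21 adjusted over the list alone (camera adjusted p = 2.3e-20, adjusted p = 0.12 with an estimated correlation). All 8 class II antigen-presentation genes rose, 8 also adjusted over the list alone, with H2-DMb2 9.35-fold higher (adjusted p = 0.32 with an estimated correlation). Of 19 lymphocyte markers 7 rose, 14 adjusted over the list alone, including Cd79b (17.3-fold), with adjusted p = 0.49 with an estimated correlation. Of 5 neutrophil markers 4 rose (adjusted p = 0.32 with an estimated correlation). Of 24 macrophage markers 9 rose, with 12 adjusted over the list alone (adjusted p = 0.55 with an estimated correlation), and of 18 cytokines and chemokines 5, among them Il1b (18-fold), Cxcl1 (9.52-fold) and Ccl8 (10.3-fold). Of 15 progenitor and fibroblast markers 6 rose, 7 adjusted over the list alone, such as Ly6a (2.62-fold, 5 of 5) and Sfrp4 (5.78-fold, 5 of 5). Of 31 collagen and matrix genes 5 rose, including fibronectin (Fn1, 4.44-fold), and 7 fell, including Col5a3 (2.42-fold lower). Of 20 genes of fatty acid synthesis 3 fell, Scd2, Fasn and Dgat2, and 4 adjusted over the list alone (adjusted p = 0.53 with an estimated correlation). Of 23 genes of cholesterol synthesis 6 fell, such as Sc5d, Insig1 and Lss, and 9 adjusted over the list alone (adjusted p = 0.53 with an estimated correlation). Lep and Lpl fell among 23 adipocyte genes, and Kcnk3 and Otop1 among 12 thermogenic genes. Other called members were Mmp3 and Mmp23 of 19 matrix proteases, and Plod2, P4ha1 and Pycr1 among 4 of 17 proline metabolism genes. Also called were Wt1 of 11 mesothelial markers, Lyve1 of 13 endothelial markers, Gsr (higher), Gstm1 and Gstm2 (lower) of 18 glutathione genes. Others were Nfil3 of 15 clock genes, Ier3 and Junb of 13 immediate early genes, Psat1 (lower), Xbp1 and Creld2 among 4 of 19 stress response genes, and Hbegf (lower) of 10 EGFR family genes.

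Immunoglobulin gene segments and Saa1 and Saa2 held large rises, with Ighg1 at 1360 ± 2720 against 6.16 ± 7.34 CPM, and reads of these close relatives are uncertain. KO library 3 held low values of most of these immune genes, with Cd79a at 5.23 CPM. Epididymis markers summed to 15100 CPM in KO library 1 and 14700 CPM in WT library 2, against at most 6.46 and 17.8 CPM in the other libraries of these groups. Summed testis markers reached 458 CPM in WT, beside lower sperm genes such as Spesp1 and Tex33. In all, 1287 genes were higher and 893 lower among 14536 tested. The edgeR count was 0 in a fit of these 2 groups (1547 at an unadjusted p under 0.05), 2586 by DESeq2, 4210 without KO library 3, 774 without KO 4, 1065 without KO 5 and 1250 without WT library 5. Without the 3 chow libraries over 10000 CPM of epididymis markers it was 1804, of which 1399 were among the 2180.

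**Figure D4:**
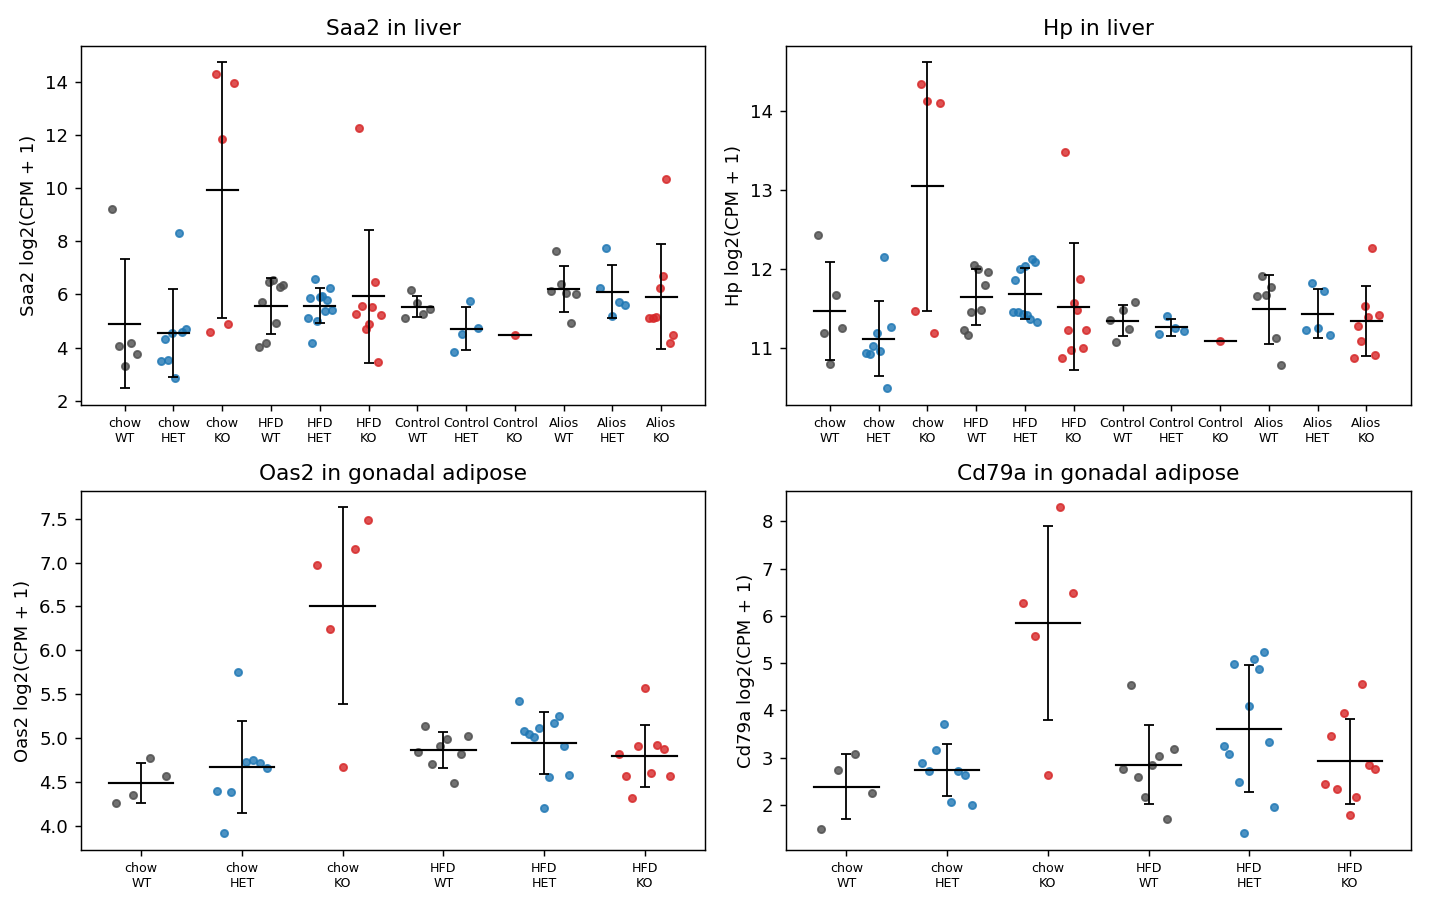
Saa2 and Hp in liver and Oas2 and Cd79a in gonadal adipose tissue as log2(CPM + 1) (y axis) in each library by diet and genotype; bars give the mean and SD. Among KO mice on chow the libraries spread widely, with Saa2 at 23.2 to 20100 CPM in liver and Cd79a at 5.23 to 313 CPM in adipose tissue.

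In heterozygous adipose tissue Pepd lay below the WT mean in every library on both diets without passing the test, and Atp2a1 alone was called. On chow edgeR called 0 genes, with 623 at an unadjusted p under 0.05 and 12 by DESeq2. Pepd was at 57.9 ± 7.13 CPM in HET and 83.8 ± 17.8 in WT (log2 -0.54 ± 0.24, edgeR adjusted p = 0.97), and 2 genes were called without WT library 2, 2 without WT 4 and 3 without WT 5. On HFD Pepd was at 61.6 ± 13.8 against 103 ± 9.3 CPM, below every WT library in 11 of 11, the mouse labelled HET included, yet did not pass the test over 14536 genes (log2 -0.74 ± 0.19, edgeR adjusted p = 0.49). The muscle calcium pump gene Atp2a1 was the gene called on HFD (0.365 ± 0.235 against 17.9 ± 49.9 CPM, edgeR adjusted p = 0.022), and its WT mean rested on a library at 141 CPM, WT library 2, which held 1090 CPM of summed muscle markers. Without WT library 2 and WT library 6, the latter with 48400 CPM of hepatocyte markers, 0 genes were called by edgeR (330 at an unadjusted p under 0.05), and DESeq2 on all libraries called 1 other gene (590 at an unadjusted p under 0.05).

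On HFD, KO adipose tissue differed from WT in 5 genes. Pepd was 4.09-fold lower, and Fcna, which encodes a ficolin of the complement lectin pathway, was 2.17-fold higher (67.2 ± 21.4 against 31 ± 6.78 CPM, edgeR adjusted p = 0.011), above every WT library in 9 of 9. The muscle genes Atp2a1, Tnnt3 and Neb were lower (edgeR adjusted p = 0.011, 0.033 and 0.011), beside the muscle markers in WT library 2. Over the list alone, 5 of 6 muscle markers and 8 of 13 epididymis markers were lower, the latter beside 1860 and 1120 CPM of summed epididymis markers in WT libraries 5 and 8. Adjusted over the list alone, 6 of 18 genes of glucose metabolism were also lower (camera adjusted p = 0.0018, adjusted p = 0.47 with an estimated correlation), with 0 over all genes tested. Without WT libraries 2 and 6 Pepd alone was called, and Tnnt3 then had a log2 change of 0.00. The count was 23 by DESeq2, of which 3 were among the 5, and 1521 genes had an unadjusted p under 0.05.

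Between HFD and chow in WT adipose tissue, Postn, Col6a3 and Cpt1a were among the genes higher on HFD, and genes of epididymis and liver stood among the largest changes. Of 29 named genes called, 0 kept their edgeR call without each of the 4 chow libraries. Postn was 2.35-fold higher (296 ± 85.2 against 126 ± 29.5 CPM, edgeR adjusted p = 0.028, above every chow library in 8 of 8), Col6a3 2.08-fold and Cpt1a 1.74-fold higher (edgeR adjusted p = 0.013). Acaca, the first enzyme of fatty acid synthesis, was 2.27-fold lower (edgeR adjusted p = 0.022). The lowest genes were epididymal, such as Wfdc13 (0.203 ± 0.199 against 667 ± 1330 CPM), Defb37 and Rnase9, beside 14700 CPM of epididymis markers in chow WT library 2. The highest, such as Apoa4 and Habp2, are liver genes, beside 48400 CPM of hepatocyte markers in HFD WT library 6, and Ucp1 rose to 9.88 ± 24 CPM with a highest library at 69.2. Of 31 collagen and matrix genes 3 rose, 4 adjusted over the list alone (adjusted p = 0.56 with an estimated correlation). Of 25 genes of fatty acid oxidation 2 rose, 8 adjusted over the list alone (adjusted p = 0.56 with an estimated correlation). With 0 or 1 called over all genes tested, 12 of 19 matrix proteases, 7 of 24 macrophage markers and 11 of 18 cell cycle genes were higher adjusted over the list alone (adjusted p = 0.56 with an estimated correlation for each). In all, 233 genes were higher and 432 lower. The count was 3 without chow WT library 2, 1697 without WT 3, 406 without WT 4, and 1296 without WT 5. It was 0 by edgeR in a fit of these 2 groups (2695 at an unadjusted p under 0.05) and 1347 by DESeq2, 784 of them higher. Ltf, Nqo1, Ces5a and Serpina16 changed direction without WT library 2.

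The KO effect in adipose tissue differed between the diets for 920 genes, 677 of them lower on HFD than on chow. Of 23 interferon-stimulated genes 20 passed, all lower on HFD, and 23 adjusted over the list alone, a list call that held with an estimated correlation (camera adjusted p = 5.9e-28, adjusted p = 0.027 with an estimated correlation). Rtp4 had a log2 difference of -2.19 ± 0.36 (edgeR adjusted p = 0.00084) and Oas2 of -2.37 ± 0.40 (edgeR adjusted p = 0.00097). Of 8 class II antigen-presentation genes 7 passed (adjusted p = 0.18 with an estimated correlation). Of 19 lymphocyte markers 6 passed, and 16 adjusted over the list alone, with Cd79a at -4.39 ± 1.01 (adjusted p = 0.62 with an estimated correlation). Ccl8, Il1b and Cxcl1 were among 4 of 18 cytokines that passed. Fasn and Scd2 were higher, at 1.90 ± 0.56 and 1.70 ± 0.53. Of 43 named genes 15 kept their call without each of the 9 chow libraries, among them Ccl8, Cd79a, H2-Aa, Oas2 and Rtp4. The count was 2650 without chow KO library 3, 302 without KO 4, 462 without KO 5, 595 without WT 3, 1406 without WT 4 and 417 without WT 5. It was 220 in a fit of these 4 groups, 645 without the 3 libraries over 10000 CPM of epididymis markers and 556 without HFD WT libraries 2 and 6.

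**Figure D5:**
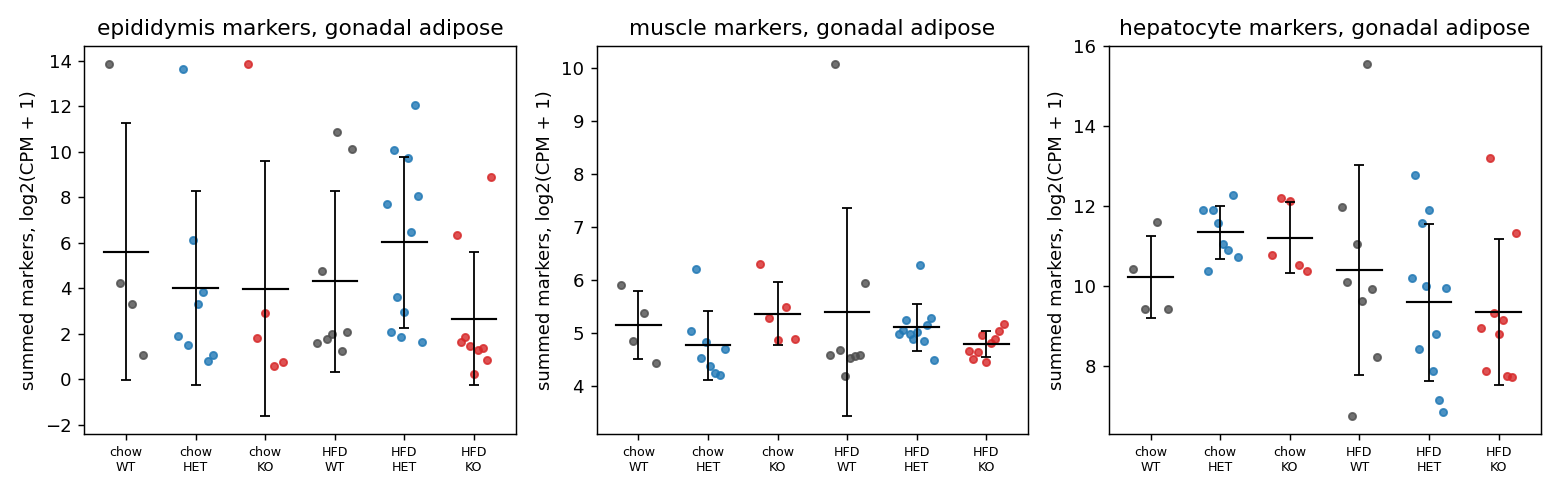
Summed epididymis, muscle and hepatocyte marker levels as log2(CPM + 1) (y axis) in each gonadal adipose library by diet and genotype; bars give the mean and SD. The high points are chow KO 1, HET 2 and WT 2 for epididymis (15100, 12700 and 14700 CPM), HFD WT 2 for muscle (1090 CPM) and HFD WT 6 for hepatocytes (48400 CPM).

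Among the gene lists tested in liver, those of lymphocyte markers, cholesterol synthesis, glucose metabolism, bile duct markers, pancreas markers, oxidative phosphorylation, erythrocyte genes, clock genes and immediate early genes had 0 members called by edgeR over all genes in any of the 11 comparisons planned. In adipose tissue this held for glucose metabolism, oxidative phosphorylation, hepatocyte markers, erythrocyte genes and cell cycle genes in the 6 comparisons planned.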

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

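Of the tests in this part, those on a DNA difference linked to the Pepd allele, on shared reads by fold change (narrowed to genes of the same subfamily after a first outcome over both subfamilies was seen, which spoke for shared reads for Cyp2c29 and Cyp2c55 and, once narrowed, was left undecided for Cyp2c29), on immune cells by the acute-phase list, on a state shared by the tissues of a mouse, on fewer libraries in adipose tissue, on residual Pepd between tissues, and the splits of the chow KO and WT livers were chosen after the result was seen; the other tests were written before.

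Cyp2b10, Cyp2c29 and Cyp2c55 were higher in KO livers on HFD and on Alios. A DNA difference near Pepd that raises Cyp2b10 on its own chromosome copy would act in HET mice as well, but HET livers on Alios held 2.6 % of the KO mean of Cyp2b10, which argues against it; a linked variant that acts only with both copies was not tested. Reads shared with related genes are argued against for Cyp2b10. Its log2 change exceeded that of the highest other tested gene of its subfamily, Cyp2b13, by 6.07 ± 1.10 on HFD and 7.89 ± 1.09 on Alios. For Cyp2c29 the test by fold change cannot decide (0.58 ± 0.57 above Cyp2c55 on HFD, 0.64 ± 0.60 above Cyp2c54 on Alios). In CPM Cyp2c29 rose by 2410 on HFD and 2370 on Alios. The highest other rise, of Cyp2c50, was 428 and 374 CPM. That is 17.8 % on HFD and 15.8 % on Alios, between the bounds of 10 and 100 set for the test. These amounts argue against any single tested relative as the source of most of the Cyp2c29 rise, but a shared part stays open. Shared reads stay open for Cyp2c55 (-0.58 ± 0.57 and -0.67 ± 0.46 against Cyp2c29). Activation of the constitutive androstane receptor, a nuclear receptor that induces Cyp2b10, may be the biological source, but the other known targets gave no shared direction (25 of 30 tested, median log2 change -0.11 on HFD and -0.14 on Alios, fry p = 0.95 and 0.54), and members going both ways decide nothing, so this stays open. The KO library on Control, which entered no comparison, held 60 CPM of Cyp2b10 against 0 to 6.61 in the 9 other Control libraries, 3500 CPM of Cyp2c29 against 186 to 942 and 16.4 CPM of Cyp2c55 against 2.06 to 12.9.

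Acute-phase and immune genes were higher in KO livers on chow, unevenly between mice. More immune cells alone in the liver pieces would leave the median change of the acute-phase list, made mostly by hepatocytes, at 0 or lower. Instead 20 of 20 members were higher and 8 were called. By camera with an estimated correlation the list as a whole was not called (adjusted p = 0.24), but that test called 0 of 30 lists in this comparison. Its lack of a call therefore decides nothing, and more immune cells beside a response of hepatocytes stay open. A state of the individual mouse, such as an infection, may be a candidate source. Over 16 chow mice, with the genotype means removed, the liver acute-phase score and the adipose interferon-stimulated score had Pearson's r = 0.66 (permutation p = 0.018, adjusted 0.036 over 4 relations). Spearman's rho was 0.44 (permutation p = 0.078, adjusted 0.16), and r was 0.69 (permutation p = 0.00081) without WT 1 and KO 2. The interferon-stimulated scores of the 2 tissues had r = 0.59 (permutation p = 0.015, adjusted 0.036) and rho = 0.58 (permutation p = 0.02, adjusted 0.08). On HFD, over 28 mice, r was 0.18 (permutation p = 0.32) and rho 0.07 (permutation p = 0.72), and the interferon-stimulated scores had r = 0.32 (permutation p = 0.088, adjusted 0.12), or 0.42 (permutation p = 0.033) without 2 mice, and rho = 0.3 (permutation p = 0.12). A KO effect that varies between mice and a state unrelated to genotype cannot be separated with 5 KO mice, and chance was not excluded: 8 of 100 splits of these libraries gave at least the 376 genes observed, up to 1531 with WT 4 in place of KO 4, several times the real count, which points to a structure of the samples.

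In adipose tissue, 665 genes differed between HFD and chow in WT mice. Epididymis tissue in chow WT library 2 goes with much of this. The library was the highest of the 4 chow WT libraries for 64.6 % of the 432 lower genes, and 3 genes were called without it. It was also the lowest of the 4 for 55.8 % of the 233 genes higher on HFD, a share that the test did not use. A loss of calls from fewer libraries alone would also follow the omission of another chow WT library, but the lowest such count was 406, which argues against it. A real effect of the diet on WT adipose tissue stays open.

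Of 100 splits of the same libraries for each comparison, the real grouping counted among them, at least as many genes were given by 1 for KO on HFD in liver (190, the highest other split 38), 4 for HFD against chow in WT liver (207, other 1114), 3 for the difference of KO effects in liver (16, other 289), 1 for KO on Alios (26, other 7) and 3 for HFD against chow in WT adipose tissue (665, other 1558). None of these shares is adjusted for the number of comparisons. At an unadjusted share, chance was excluded for the counts of KO on HFD and on Alios, which no other split drawn reached. For the other 3 the share was under 0.05 too, but chance was not held to be excluded, since other splits exceeded the real counts, those reaching 1114 and 289 several times over, which points to a structure of the samples, and the liver difference fell to 0 (edgeR, 1674 at an unadjusted p under 0.05, 168 by DESeq2 on all groups) in a fit of its 4 groups. For counts of 1 in HET livers on HFD (8 splits, other 185), Alios (11 splits, other 78) and Control (11 splits, other 8), the splits did not exclude chance for the count. They do not bear on the gene, Pepd, which was below every WT library in 11 of 11, 5 of 5 and 4 of 4 HET livers, the mouse labelled HET included. Chance was not excluded in adipose tissue for the count of KO on chow (17 splits, 2180 genes, other 5767), KO on HFD (15 splits, 5 genes, other 439), HET on HFD (53 splits, 1 gene, other 495) and the difference of KO effects (12 splits, 920 genes, other 5446). Here too, splits that called several times the real count point to a structure of the samples, and they do not bear on single genes: on HFD, Pepd was below and Fcna above every WT library in 9 of 9 KO libraries. For the comparisons with 0 genes by edgeR, HET on chow in liver and adipose tissue, Alios against Control in WT and the difference of HET effects, the splits say nothing about chance, since all 100 must give at least 0; the highest gave 206, 2317, 115 and 51. DESeq2 called 0, 12, 0 and 0 genes there, and 494, 623, 976 and 314 had an unadjusted p under 0.05.

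The KO effect differed between HFD and chow for 16 genes in liver and 920 in adipose tissue by the test of the difference. In 9 KO mice measured in both tissues on HFD, residual Pepd was 24.5 % ± 6.5 of the WT mean in adipose tissue and 3.35 % ± 1.19 in liver (SD), higher in adipose tissue in 9 of 9 (two-sided exact permutation p = 0.0039, the smallest that 512 sign changes can give).

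Single libraries stood apart from the rest of their group in 25 of 80 tests, each of 1 measure in 1 group. Chance would give about 4 only if the measures were independent and normally spread, which was not tested. The HFD HET groups of 11 libraries and the KO library on Control were left out of these tests. Pepd was at 49.8 CPM in chow WT liver 4 (others 40.5 to 42), 25.8 in Control HET 4 (20.4 to 21.2) and 0 in Alios KO 8 (2.15 to 3.16), the library of 42692 counts. Cyp2b10 was at 73 CPM in chow KO 4 (15.1 to 27.2), 21.2 in chow HET 8 (1.16 to 5.49) and 6.61 in Control WT 3 (0 to 1.55). The liver acute-phase score, a mean of log2 values, was 9.1 in chow HET 6 (7.38 to 7.67), 10.65 in HFD KO 2 (7.49 to 8.27), 9.48 in chow WT 1 (7.34 to 7.79) and 8.92 in Alios WT 2 (7.76 to 7.95). Skeletal muscle markers in liver summed to 205 CPM in chow KO 5 (8.24 to 17.7), 318 in chow WT 3 (7.66 to 12.2), 16.2 in HFD WT 8 (7.14 to 10.4), 94.2 in HFD KO 7 (8.42 to 13.9), 175 in Alios WT 2 (7.89 to 14.3), 736 in Alios KO 2 (0 to 14.6) and 185 in Control WT 1 (6.25 to 20.4). In adipose tissue, epididymis markers summed to 15100 CPM in chow KO 1 (0.472 to 6.46), 12700 in chow HET 2 (0.721 to 68.5), 14700 in chow WT 2 (1.11 to 17.8) and 481 in HFD KO 9 (0.157 to 80.9). Muscle markers there reached 73.2 CPM in chow HET 2 (17.5 to 31.6) and 1090 in HFD WT 2 (17.2 to 60.3), and hepatocyte markers 9390 in HFD KO 3 (211 to 2570) and 48400 in HFD WT 6 (107 to 4060).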

How the results depend on the processing

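Fits without libraries of high epididymis, muscle or liver markers, without the mouse labelled HET and without Alios KO 8 were chosen after seeing the data. With RLE size factors 444 of 449 values of named genes kept their side of the threshold, with DESeq2 398 of 428, and with no filter 400 of 449. With a mean of at least 1 CPM 436 of 440 did, and in fits of only the groups compared 203 of 366. Such fits take the spread from fewer libraries and from those groups alone, and which of these moved the calls was not tested. The count for KO on Alios rose in such a fit. Except where a cause is named, the cause of a change was not tested. Depth limits low genes most: Alios KO 8 held 42692 counts. A planned sex covariate was not run, since Ddx3y was expressed in every library.

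By DESeq2, 16 genes were called for HET on HFD in liver, 168 for the liver difference of KO effects, 65 for KO on Alios, and in adipose tissue 12 for HET on chow, 23 for KO on HFD and 1347 for HFD against chow in WT, 784 of them higher. Tnnt3 moved to 0.12 (KO on HFD) and -0.12 (diet), Atp2a1 in HET to 0.31, and in HET mice between diets Lcn10 to -0.28 and Rnase10 to 0. RLE size factors gave 40 for KO on Alios. No filter gave 7 for HET on chow and 4 for the difference in liver, and 8 for KO and 4 for HET on HFD in adipose tissue. A mean of at least 1 CPM gave 5 for HET on chow in liver and 3 for HET on HFD in adipose tissue. Only the groups compared gave in liver 1 for KO and 1 for HET on chow, 80 for KO and 0 for HET on HFD, 82 for the diet in WT, 0 for the difference, 53 for KO and 0 for HET on Alios (1133, 1674 and 181 at an unadjusted p under 0.05 beside the counts of 0). In adipose tissue they gave 0 for KO on chow, 1 for KO and 0 for HET on HFD, 0 for the diet in WT and 220 for the difference (1547, 605 and 2695 unadjusted). All 12 liver groups in a fit gave 617 for KO and 8 for HET on chow, 2 for HET on HFD, 269 for the difference, 52 for KO and 0 for HET on Alios and 0 for HET on Control (274 and 298 unadjusted).

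Same-numbered libraries came from 0 shared mice and correlated at -0.67 to 0.88, and in no comparison did every pair exceed 0.1 or every library correlate best with its own number, so the numbers were taken to share only a number. The replicate block gave 209 for KO on chow, 100 and 769 for the diet in WT and HET, 6 for the difference and 8 for KO on Alios in liver. In adipose tissue it gave 1 for KO and 0 for HET on HFD (389 unadjusted), 2 for the diet in WT and 495 for the difference, with Lcn8 at -0.68 in HET. The run of mouse numbers as a covariate gave 9 for the liver difference and 3 for KO and 0 for HET on HFD in adipose tissue (703 unadjusted).

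An adjusted p under 0.01, a stricter threshold, left 79, 15 and 9 genes for KO on chow, HFD and Alios, 29 and 660 for the diet in WT and HET and 0 for the difference in liver. In adipose tissue it left 788 and 1 for KO on chow and HFD, 0 for HET on HFD, 0 and 2992 for the diet in WT and HET and 225 for the difference. Without chromosome 7, which holds Pepd, 0 genes were left for HET on HFD, Alios and Control in liver, and 2 for KO and 0 for HET on HFD in adipose tissue. Of 194 list calls by camera in the comparisons planned, 1 held with an estimated correlation, and fry called 46. The diet comparisons in HET mice are not in these counts.

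Without the libraries over 10000 CPM of epididymis markers, 5 genes were called for HET on chow and 3 for the diet in WT. Ces5a then stood at 0.62, Serpina16 at 1.25, Ltf at 1.8, Nqo1 at 0.03 and Egf at 0. In HET, Defb28 stood at 4.85, Serpina16 at 2.71, Prr27 at 1.8 and Ltf at 3.21. Without the libraries with muscle or liver markers, 1 gene was called for KO on HFD, 0 for HET on HFD (330 unadjusted) and 556 for the difference, with Tnnt3 at 0 (KO) and -0.05 (diet).

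Leaving out single libraries moved the counts from 22 (KO 2) to 1055 (KO 4) for KO on chow, from 0 to 1 (WT 4) for HET on chow, from 48 (WT 1) to 188 (WT 4) for the diet in WT and from 0 to 463 (WT 4) for the difference in liver, and from 0 to 2 (Control WT 3) for Alios against Control. The count stayed at 1 for HET on HFD, Alios and Control and at 0 for the difference of HET effects. It moved from 26 to 22 for KO on Alios without KO 8, and from 1574 to 1577 for the diet in HET liver without HET 8. In adipose tissue it ran from 774 (KO 4) to 4210 (KO 3) for KO on chow, from 0 to 3 (WT 5) for HET on chow, from 3 (WT 2) to 1697 (WT 3) for the diet in WT and from 302 (KO 4) to 2650 (KO 3) for the difference, and was 1 for HET on HFD and 4538 for the diet in HET without HET 3. Without chow WT 2, AY761185 stood at 1, Ces5a at 0.67, Serpina16 at 1.29, Ltf at 1.8, Nqo1 at 0.03 and Egf at 0. The lowest values without another chow WT library were -10.21, -10.18, -9.85, -6.18, -2.13 and -3.45. The 0 counts of this paragraph are by edgeR, with up to 1856 genes at an unadjusted p under 0.05.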

Other observations

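The comparison of HFD with chow in HET mice and the test of a smaller diet response were chosen after the data were seen. In HET livers, 11 on HFD and 8 on chow, lipid droplet and collagen genes were higher on HFD, and genes of cholesterol synthesis were lower. Apoa4 was 10.6-fold higher (log2 3.40 ± 0.49, edgeR adjusted p = 5.2e-06), the droplet coat gene Plin2 2.38-fold (edgeR adjusted p = 4.2e-06) and Postn 3.08-fold (edgeR adjusted p = 3.4e-05), each in 11 of 11, the mouse labelled HET included, and Gpnmb was 17.8-fold higher, with 5 of 24 macrophage markers called higher (adjusted p = 0.52 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 3.32-fold lower (edgeR adjusted p = 0.00077, 11 of 11). It belongs to a list of 18 genes of bile acid and sterol transport, of which 8 fell and 1 rose (adjusted p = 0.33 with an estimated correlation). Of 28 collagen and matrix genes 19 rose, and 21 rose and 1 fell adjusted over the list alone (adjusted p = 0.13 with an estimated correlation). Of 13 stellate cell markers 5 rose and 1 fell, and 10 rose and 1 fell adjusted over the list alone (adjusted p = 0.13 with an estimated correlation). Of 13 endothelial markers 3 rose (adjusted p = 0.15 with an estimated correlation), and of 19 xenobiotic cytochromes P450 12 fell and 2 rose (adjusted p = 0.21 with an estimated correlation). Of 13 lipid droplet genes 9 rose (adjusted p = 0.13 with an estimated correlation), and of 24 genes of cholesterol synthesis 10 fell, 15 adjusted over the list alone (adjusted p = 0.3 with an estimated correlation). Tnni2, Actn3 and Pvalb were lower on HFD (edgeR adjusted p = 0.012, 0.0052 and 0.028), beside 1970 and 1040 CPM of summed muscle markers in chow HET 1 and 8 and 1170 CPM in HFD HET 5. In all, 771 genes were higher and 803 lower, and of 100 splits 1, the real grouping, gave as many as the 1574 (the highest other 87), so chance was excluded at a share not adjusted for the number of comparisons.

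In HET adipose tissue, macrophage and cell cycle genes were higher on HFD, and genes of fatty acid synthesis, oxidative phosphorylation and adipocytes lower. Gpnmb was 12.7-fold higher (edgeR adjusted p = 1.7e-05), Itgax 8.05-fold and Cd68 5.2-fold (edgeR adjusted p = 2e-05), each above every chow library in 11 of 11. Acaca was 3.73-fold lower (edgeR adjusted p = 6e-07) and Fasn 3.51-fold lower. Of 24 macrophage markers 17 rose and 1 fell, 18 and 1 adjusted over the list alone (adjusted p = 0.4 with an estimated correlation), and of 36 genes of oxidative phosphorylation 33 fell, 34 adjusted over the list alone (adjusted p = 0.44 with an estimated correlation). Of 18 cell cycle genes 17 rose (adjusted p = 0.4 with an estimated correlation). Of 20 genes of fatty acid synthesis 11 fell, 14 adjusted over the list alone (adjusted p = 0.4 with an estimated correlation). Of 23 adipocyte genes 12 fell, and 14 fell and 1 rose adjusted over the list alone (adjusted p = 0.78 with an estimated correlation). Epididymis markers reached 12700 CPM in chow HET 2 and 4270 CPM in HFD HET 9. In all, 2268 genes were higher and 2734 lower, and of 100 splits 1, the real grouping, gave as many as the 5002 (the highest other 2018), so chance was excluded at the same unadjusted share.

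Genes lower in KO than in WT livers on HFD were often genes that HFD raised in HET livers, a comparison with no library in common. Of the 127 lower genes 58 were among the 771, where independent lists would share 8.9, among them Col1a1, Col3a1, Cidea, Plin2 and Usp18, and 2 were among the 803 lower on HFD (9.2 for independent lists). Of the 63 higher genes 17 were among those 803 (4.6 for independent lists), including Cyp2c50 and Egfr. A smaller response to HFD in KO livers may be a candidate explanation, as a hypothesis found in the same data. The test of the difference itself called 16 genes, with Col1a1 not among them. A lower level in KO livers that is unrelated to diet would share genes in the same way. Cidea, for example, was also low in KO livers on chow, at 0.319 ± 0.5 against 16.8 ± 19.7 CPM in WT, a difference that was not called.

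KO livers on HFD and on Alios, which share no library, had 7 called genes higher in both (0.08 for independent lists): Chic1, Cyp2b10, Cyp2c29, Cyp2c55, Lad1, P2rx3 and Zfp574. Another 7 were lower in both (0.14 for independent lists): Cgref1, Defb1, Mcam, Osbpl3, Pepd, Postn and Sema3b, and 0 went opposite ways by edgeR (0.23). Between KO livers on chow and on HFD 6 higher genes were shared (1.6 for independent lists) and 2 lower (1.2), with 1 in opposite directions (3.7). On chow, 121 genes were higher in both liver and adipose tissue of KO mice, among them C1qa, Cd74, H2-Ab1, S100a9, Saa3 and Zbp1. Independent lists would share 23, but most of these WT and KO mice were measured in both tissues. That number is therefore no fair baseline. The 7 lower in both were close to the 5.7 for independent lists, and 2 went opposite ways (24).

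In the mouse labelled HET on HFD whose Pepd was at the KO level in both tissues, Cyp2b10 in liver was at 174 CPM, where the other HET livers on HFD reached at most 3.94, and Cyp2c29 was at 3930 CPM against at most 1020. Refits of liver without it covered HET against WT on HFD and HFD against chow in HET. There 75 of 75 called values of named genes kept their side of the threshold, and 1 gene was called for HET on HFD. The other liver comparisons on chow and HFD share the estimate of the spread with this mouse. They were not refitted with only this mouse left out.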
